A study of Mus musculus with 8 samples.

How the data were processed

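Small RNA was measured by sequencing in 8 hearts of wild-type C57Bl6/J mice aged 4 to 6 weeks (adult in the labels), 4 female and 4 male, with 1 library per heart. Per the labels' protocols, each heart was extracted separately with a miRNA isolation kit and the RNA was enriched for molecules under 200 nt. The 4 libraries of each sex are therefore separate animals. The sex and the replicate number of each library came from the labels.

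The deposited tables, 1 per heart, hold read counts per miRNA hairpin entry, split per the file headers into reads on the mature 5' arm, reads on the mature 3' arm and other reads on the hairpin. The submitters' processing notes name STAR and the mouse build mm10, without a version or a role. The counting tool, the trimming and the filters are not given in the sources used here. The entries come from 3 species (mouse, human and rat), so a read of a mouse heart can be listed under a human or rat hairpin where that entry matched. Mouse entries held 89.7% ± 2.04 of all counts in the female libraries and 90.6% ± 0.830 in the male libraries (SD, n = 4). Rat entries held 6.85% ± 1.71 and 6.02% ± 0.828 (SD, n = 4). The deposited counts in the columns for reads unique to 1 entry held no value from 1 to 9 and 1382 values from 10 to 19, which are the values a minimum of 10 copies per distinct sequence would leave. Low counts are therefore less precise than their size alone would give, and a count of 0 sets no upper limit. Reads that match the mature sequence exactly made up 24.8% ± 0.971 of mature counts in female and 25.7% ± 1.07 in male libraries (SD, n = 4). Whether the rest were length or sequence variants or reads of another hairpin was not examined.

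Total counts per library ran from 29900500 to 38894987. Reads on a hairpin outside both mature arms were left out of library sizes and tests. No 2 libraries looked like copies of each other, since over all pairs the smallest chi-square per degree of freedom across miRNAs was 616.7, and log2 CPM correlated across miRNAs with r from 0.981 to 0.993. miRNAs are not independent replicates in such an r. By the chi-square, female replicate 3 lay furthest from the other hearts, at 3395 to 5578, against 616.7 to 3573 in pairs without it. Its TMM factor was 1.41, against 0.845 to 1.06 in the other hearts. It was kept in the main tests.

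The tables list hairpins and arms, not mature miRNAs, so a unit of analysis had to be set after the tables had been seen. Entries of the same name and arm from the 3 species were summed. Numbered copies of a hairpin, such as mir-26a-1 and mir-26a-2, were summed where under 50% of the reads of the mouse entries were unique to 1 copy. This gave 683 miRNAs, 568 with a mouse entry and 115 with a human or rat entry alone, which held 7.55% of mature counts. The 115 are marked as rat or human entries in the text. Copies could hold nearly the same counts, as the 3' entries of mir-24-1 and mir-24-2 did with 225387 and 225396 over all libraries. The sources used here do not say whether shared reads were divided among copies or counted at each. If counted at each, the levels and shares of summed miRNAs are too high. The plan had taken the deposited rows as they stand as the first choice and summing as the alternative. The summed unit was used because the tables do not hold 1 row per mature miRNA. It was settled after exploratory fits of 4 units (summed, as deposited, mouse entries only, exact matches) had been looked at, and the rule for copies was changed once after such a fit, from all entries to mouse entries. The counts of calls under all 4 are given in the closing section.

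Hairpin positions are GRCm38, the assembly of mm10, from the RefSeq table and GENCODE vM21. Of 461 mouse hairpins listed, 460 matched a RefSeq gene by name. Several hairpins overlap another one on the opposite strand. The sources used here do not say whether counting used strand, so reads of such partners cannot be told apart.

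Female and male libraries were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, design with sex alone, TMM factors, R 4.3.3). Its filterByExpr function with a minimum count of 10 and a minimum total of 15 kept 562 miRNAs, which held 99.9985% of mature counts. Adjusted p is the Benjamini-Hochberg value over these 562, with a threshold of 0.05. Fold changes are log2 values of female minus male, and their standard errors were taken as the fold change divided by the square root of the quasi-likelihood F value. Levels are CPM as the cpm function of edgeR gives them, scaled by TMM, as mean ± SD. Shares are percent of mature counts without such scaling. The number of miRNAs with at least 10 counts, the share of the 10 most abundant and the summed share of muscle miRNAs were compared with a two-sided exact permutation test over the 70 arrangements of 4 against 4, whose smallest p is 0.0286. The log2 ratio of 5' to 3' arm counts, with a pseudocount of 0.5, was compared with limma 3.58.1 for the 111 hairpins with a mean of at least 10 counts on both arms.

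Lists of miRNAs by cell type, family, cluster and chromosome were fixed before the data were examined. The 20 lists were tested with camera at a preset correlation of 0.01 and adjusted over the 20. Camera with an estimated correlation and fry were run beside it. The list of X-chromosome miRNAs was taken from the positions. The rule for the miRNAs named, also fixed before, takes all past the threshold and, with fewer than 20, the 24 with the smallest p. It adds the 10 most abundant, all tested muscle, erythroid and leukocyte miRNAs, and up to 4 with the smallest p in each list. Any other name is said to have been chosen after its values were seen. Not every miRNA under the rule is described below.

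On simulated counts for the 562 miRNAs, with the means, library sizes and dispersions of these libraries, the edgeR test found 17.2% of miRNAs changed 1.5-fold, 49.7% changed 2-fold and 84.8% changed 4-fold when 200 miRNAs were changed, and 2.14% of its calls were unchanged miRNAs. With 20 changed it found 0.500%, 15.0% and 76.0%. The list test found a list of 10 miRNAs changed 2-fold at an unadjusted p under 0.05 in 10 of 10 simulations. That list was the same each time, the first 10 by name, which are let-7 entries. It does not show how often other lists of 10 would be found. The simulated miRNAs varied independently of each other. The list result therefore does not show how the test does where members vary together, or after adjustment over the lists. The arm test found 79.2% of ratios changed 4-fold, and 6.59% of its calls were unchanged.

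Alternatives were other scaling factors (RLE, upper quartile, library size alone), other filters, DESeq2 1.42.0, limma-voom, a replicate block, exact-match counts, the unsummed rows, the 10 most abundant miRNAs left out, other cutoffs for detection, abundance and arms, and each library left out in turn. Mouse entries alone, the muscle share without both miR-1 entries, arm ratios from exact matches, and the block together with an estimated correlation were added after seeing the data.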

Results

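The series measured miRNAs in whole hearts of C57Bl6/J mice, called adult in the labels at 4 to 6 weeks, to compare the sexes. Each of the 4 female and 4 male hearts gave 1 small RNA library of 29900500 to 38894987 counts on miRNA hairpins. Values are from separate animals, so the spread within a sex measures the variation between these hearts. The p of the tests on single miRNAs, shares, detected numbers and arm ratios are set against that variation. The camera p of a list at the preset correlation rests mainly on the spread across miRNAs, which are not independent replicates.

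A few miRNAs made up most of each library. The 10 most abundant held 67.4% ± 3.96 of mature counts in female and 68.5% ± 1.95 in male hearts (SD, n = 4). The 5' arm entry of mir-1b alone held 29.1% ± 4.37 in female and 28.9% ± 2.12 in male hearts (SD, n = 4). Mir1b lies on chromosome 18 (GRCm38, 10785446 to 10785567, plus strand), in an intron of Mib1 and opposite Mir1a-2 (10785481 to 10785552, minus strand), the hairpin of the muscle miRNA miR-1a-3p. The mir-1a-2 3' entry had 0 exact reads among its 134363 counts over the 8 libraries, and 3.34% of the miR-1b-5p reads matched the mature sequence listed for that entry exactly. The values of miR-1b-5p and miR-1a-3p are thus uncertain one by one, and a human mir-1-1 entry, chosen after its values were seen, held another 22263 ± 4875 CPM in female and 25023 ± 2886 CPM in male hearts (SD, n = 4).

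Next in abundance was miR-126a-3p, an endothelial miRNA from a hairpin within the Egfl7 gene on chromosome 2 (26591357 to 26591429), with 7.05% ± 0.764 of counts in female and 8.14% ± 1.79 in male hearts (SD, n = 4). The smooth muscle miRNA miR-143-3p followed with 6.03% ± 0.409 and 5.24% ± 0.5997, and miR-26a-5p with 5.14% ± 1.02 and 4.18% ± 0.782 (SD, n = 4). miR-148a-3p, let-7c-5p, miR-99a-5p, let-7i-5p, let-7f-5p and a rat entry, miR-3557-5p, each held between 2.81% and 4.19% on average in either sex. None of the 10 passed the edgeR test, and the adjusted p of all 10 was at least 0.801.

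**Figure D1:**
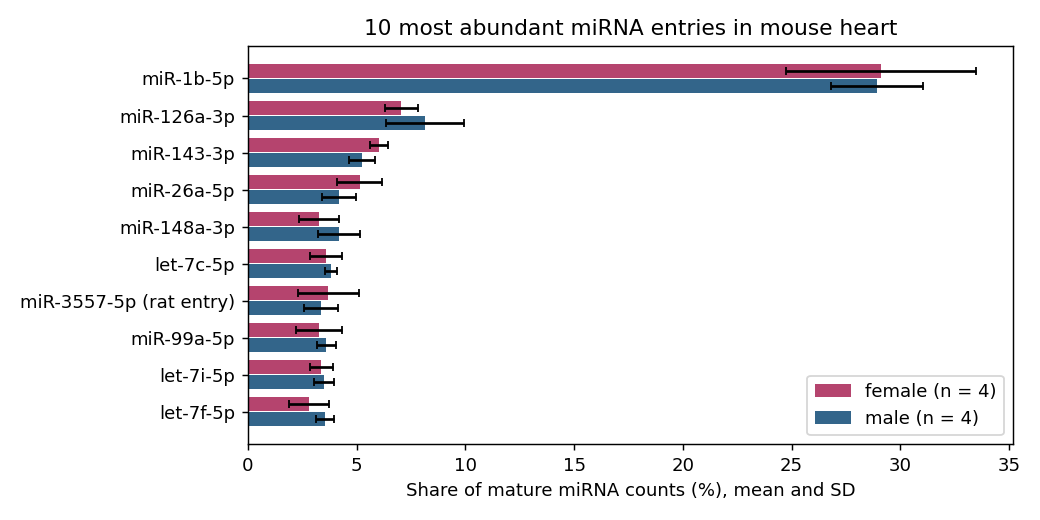
Share of mature miRNA counts (x axis, percent) of the 10 most abundant miRNA entries in female and male hearts. Bars are means and lines SD over 4 hearts. The mir-1b entry holds 29.1% and 28.9%, and the bars of the sexes overlap within their SD for most entries.

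Whether female and male hearts differed in the makeup of their miRNAs was asked first. The share of the 10 most abundant differed by -1.16 percentage points, female minus male (two-sided exact permutation test, p = 0.714, adjusted p over the 3 measures 0.886). Muscle miRNAs, which are miR-1, miR-133, miR-206, miR-208 and miR-499 together without the human mir-1-1 and rat mir-133c entries, held 29.9% ± 4.24 of counts in female and 29.5% ± 2.01 in male hearts (SD, n = 4), a difference of 0.351 points (exact permutation p = 0.886). Nearly all of this share was the uncertain miR-1b-5p entry, as with 32.9 of 33.4% in female replicate 1. The listed miR-133a-3p was not among the tested muscle miRNAs, so the share says little about miR-133. At least 10 counts were found for 570.5 ± 19.1 miRNAs in female and 556.3 ± 6.13 in male hearts (SD, n = 4), a difference of 14.3 (exact permutation p = 0.314). All 3 differences were within the spread between hearts. The sign of the first turned without female replicate 3 (0.748 points), and that of the muscle share turned without female replicate 1 (-0.828), 2 (-0.0683) or 4 (-0.104) or male replicate 3 (-0.435).

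The level of each miRNA was then compared between the sexes. Among 562 miRNAs tested, 0 were higher in female and 0 were higher in male hearts at an adjusted p of 0.05 (edgeR quasi-likelihood test). At an unadjusted p under 0.05 there were 28, 16 higher in female and 12 higher in male hearts, against 28.1 among 562 if p were uniform. Other splits of the hearts into 4 and 4, given in the closing section, had a median of 17.5. DESeq2 called 3 miRNAs higher in female hearts (miR-182-5p, miR-708-5p and let-7d-3p) and limma-voom called 0. The 4 female values lay above all 4 male values for 10 miRNAs and below them for 7. That is 17 in all, where chance gives 2.86% of miRNAs, or 16.1. The median standard error of a log2 fold change was 0.29.

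The miRNA with the smallest p was miR-182-5p, with 15.4 ± 5.11 CPM in female and 4.47 ± 1.45 CPM in male hearts (SD, n = 4). Its log2 fold change was 1.79 (SE 0.33), higher in 4 of 4 female hearts than in any male heart, with an edgeR adjusted p of 0.0968. It came under the threshold in 6 of 20 alternatives, in which its adjusted p ran from 1.33e-04 to 0.236. Its hairpin lies on chromosome 6 (30165918 to 30165992, minus strand) outside other annotated genes, in a cluster with Mir183 and Mir96. Both other members, chosen after their values were seen, had smaller values, with log2 fold changes of 0.67 (SE 0.37) for miR-183-5p and 0.24 (SE 1.20) for miR-96-5p. The second smallest p was that of miR-708-5p, from an intron of Tenm4 on chromosome 7 (96249424 to 96249532). It had 6.95 ± 2.67 CPM in female and 2.15 ± 0.914 CPM in male hearts (SD, n = 4), a log2 fold change of 1.69 (SE 0.37, edgeR adjusted p = 0.227), and the other arm, miR-708-3p, one of 1.23 (SE 0.40, adjusted p = 0.662).

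The 2 arms of let-7d, a member of the let-7 family of differentiation-linked miRNAs, lay apart in opposite directions. let-7d-3p had 408 ± 51.3 CPM in female and 263 ± 38.5 CPM in male hearts, and let-7d-5p 6213 ± 1002 CPM and 9338 ± 1116 CPM (SD, n = 4). The log2 fold changes were 0.64 (SE 0.18) and -0.59 (SE 0.18), with edgeR adjusted p of 0.481 and 0.552. All 4 female hearts lay above the male hearts for the 3' arm and below them for the 5' arm. The hairpin lies on chromosome 13 (48536012 to 48536114, minus strand) in an exon of the noncoding RNA 6720427I07Rik.

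Of the muscle miRNAs, miR-133b-3p had 48.9 ± 23.7 CPM in female and 23.0 ± 5.46 CPM in male hearts (SD, n = 4), a log2 fold change of 1.09 (SE 0.32, edgeR adjusted p = 0.481). Its neighbour on chromosome 1, miR-206-3p, was scarce, with 1.74 ± 0.642 and 1.91 ± 1.23 CPM (SD, n = 4). miR-499-5p, from an intron of Myh7b, had 5199 ± 1707 CPM in female and 4552 ± 1224 CPM in male hearts (SD, n = 4). miR-208a-3p, from an intron of Myh6, the gene of the main adult cardiac myosin in mice, had 300.2 ± 158 and 270.03 ± 67.1 CPM, and miR-208b-3p, from Myh7, had 10.4 ± 3.65 and 9.44 ± 1.95 CPM (SD, n = 4). The log2 fold changes of these 3 lay between 0.14 and 0.19, each smaller than its standard error. Of the 9 muscle miRNAs tested, 7 had the higher mean in female hearts, 0 passed over all miRNAs and 1, miR-133b-3p, adjusted over the list alone (0.0462). Whether the miR-133b-3p entry holds reads of miR-133a-3p, which was not among the tested miRNAs, was not examined. The list did not pass (camera adjusted p = 0.371).

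**Figure D2:**
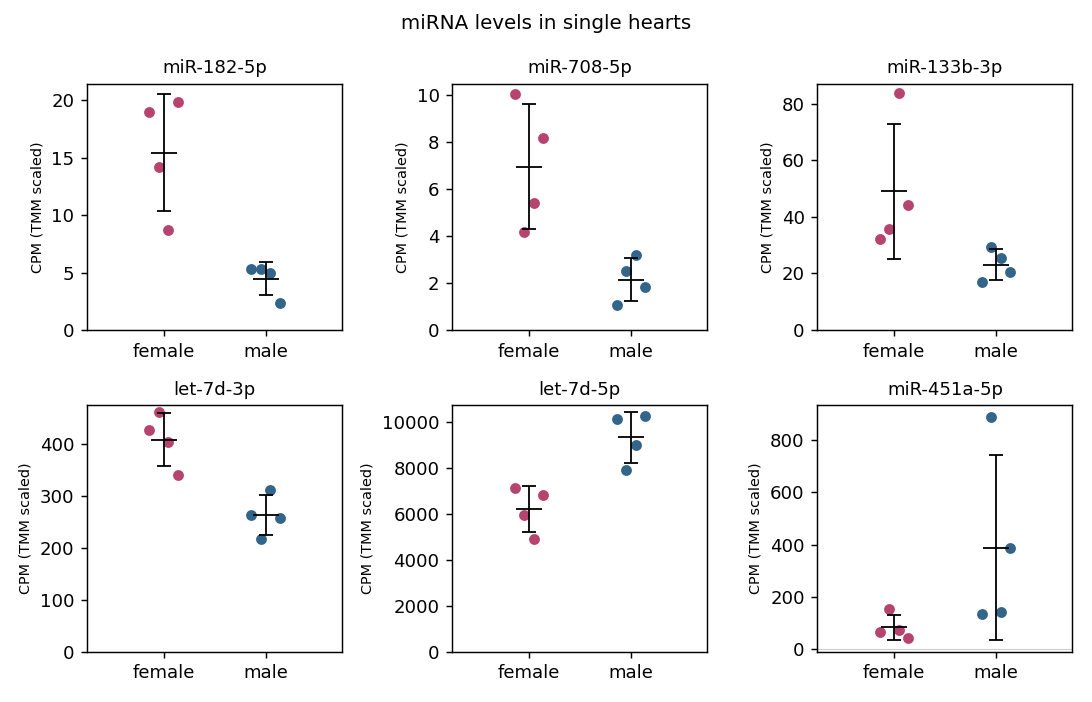
Levels of 6 miRNAs (y axis, TMM-scaled CPM) in each heart, with a point per heart and the mean and SD of the 4 hearts of a sex in black. The female points lie above the male points for miR-182-5p, miR-708-5p, miR-133b-3p and let-7d-3p and below them for let-7d-5p, and none of the 6 passed the edgeR test after adjustment.

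Of the red cell miRNAs, those of the miR-144 and miR-451a cluster varied widely between hearts of a sex. miR-451a-5p, the main miRNA of erythroid cells, had 85.1 ± 47.8 CPM in female and 388 ± 354 CPM in male hearts (SD, n = 4), with a log2 fold change of -2.19 (SE 0.60, edgeR adjusted p = 0.481). miR-144-5p and miR-144-3p, from the same cluster on chromosome 11 (Mir144 at 78073005 to 78073070 and Mir451a at 78073170 to 78073241), had log2 fold changes of -2.22 (SE 0.76) and -1.90 (SE 1.01). Male replicate 2 held the highest value of all 3. Without it, the log2 fold change was -1.27 (SE 0.45) for miR-451a-5p and -0.74 (SE 0.49) for miR-144-5p, and that of miR-144-3p turned to 0.13 (SE 0.74), while without female replicate 2 it was -3.18 (SE 1.05). miR-486a-5p and miR-486b-5p, which muscle also expresses and whose hairpins overlap on opposite strands, had log2 fold changes of -0.21 (SE 0.18) and -0.17 (SE 0.18). With library size alone as scaling these were 0.00 and 0.04. The 5' arms of their mouse entries held 237251 and 237252 exact reads over all libraries, so both may count the same reads. As miR-451a and miR-144 also share a cluster, the members of the erythroid list are not independent of each other. Of the 7 erythroid miRNAs tested, 6 had the lower mean in female hearts under TMM or RLE scaling, 5 with upper quartile factors and 3 with library size alone. Of these miRNAs 0 passed over all miRNAs and 2 adjusted over the list alone. The list's camera adjusted p was 0.107, and 0.678 with an estimated correlation. The list passed without male replicate 1 (adjusted p = 0.0147) or male replicate 4 (0.0383) and with no filter (0.0463). It also passed with the replicate block, but not when the correlation was estimated as well, as given in the closing section.

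The let-7 list held 11 tested 5' arms, with miR-98-5p among them, and all 11 had the lower mean in female hearts under TMM scaling. The list held no 3' arms, and several of those had the higher mean in female hearts, as let-7b-3p did at 1.09 (SE 0.33), or 2.79 (SE 1.36) with its few exact-match counts. The median log2 fold change was -0.26, against -0.06 over all miRNAs, and 9 of 11 were lower with RLE and 7 of 11 with upper quartile factors or library size alone. let-7f-5p had a log2 fold change of -0.45 (SE 0.31) and miR-98-5p one of -0.57 (SE 0.27), which without female replicate 3 were -0.16 (SE 0.17) and -0.29 (SE 0.14). let-7f-5p was at -0.69 (SE 0.31) without female replicate 4. None passed over all miRNAs or adjusted over the list alone. The camera adjusted p of the list was 0.0586, and it was 0.678 with an estimated correlation, which was 0.442 in this list. The list passed without female replicate 1 (0.0407), female replicate 4 (0.0180) or male replicate 2 (0.0294) and with no filter (0.0369). As for the erythroid list, it passed with the replicate block too, but not when the correlation was estimated as well.

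None of the 20 lists passed with camera at the preset correlation, with an estimated correlation or with fry. Among cell type lists, 6 of 7 endothelial miRNAs had the lower mean in female hearts (median log2 fold change -0.28, camera adjusted p = 0.371), and 7 of 9 leukocyte miRNAs did (median -0.25, adjusted p = 0.371), where 323 of all 562 miRNAs had it. With library size alone these were 4 of 7 and 5 of 9, with medians of -0.09 in both lists. Of the leukocyte miRNAs, miR-142a-5p and miR-223-5p had an unadjusted edgeR p under 0.05, with log2 fold changes of -1.11 (SE 0.44) and -0.58 (SE 0.23). The first was -0.37 (SE 0.32) without male replicate 2 and the second -0.39 (SE 0.20) without female replicate 3. The 2 leukocyte miRNAs with the higher mean in female hearts were miR-150-5p at 0.17 (SE 0.16) and miR-223-3p, the other arm of miR-223, at 0.15 (SE 0.26). The remaining ones ran from -0.67 (SE 0.38) for miR-146a-5p to -0.03 (SE 0.33) for miR-150-3p. All 4 smooth muscle miRNAs had the higher mean in female hearts (median 0.11, adjusted p = 0.448). Of 7 fibroblast miRNAs 4 did (median 0.12, adjusted p = 0.448), among them miR-199a-3p at 0.51 (SE 0.23), which shares its sequence with miR-199b-3p at 0.52 (SE 0.23), both at 0.23 (SE 0.17) without female replicate 2. The median was 0.05 for 6 members of the miR-181 family of lymphoid tissue and -0.18 for 11 epithelial miRNAs, whose mean of 0.08 had the other sign. It was 0.32 for 9 liver and neural miRNAs. Each of these 3 lists had a camera adjusted p of 0.566 or above.

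Of 45 miRNAs on the X chromosome, 25 had the higher and 20 the lower mean in female hearts (median log2 fold change 0.10, camera adjusted p = 0.371). The lower were 18 with RLE, 17 with upper quartile factors and 14 with library size alone, and the camera direction turned with at least 10 CPM in 4 libraries (adjusted p = 0.870). Of the 45, 0 passed over all miRNAs or adjusted over the list alone. The X-linked miRNAs with the smallest p were miR-374b-5p, from an intron of the noncoding gene Ftx in the X inactivation centre, at 0.88 (SE 0.31), miR-652-3p at 0.69 (SE 0.30), miR-223-5p and miR-450b-3p at 1.23 (SE 0.57). Without female replicate 2, miR-374b-5p was at 0.51 (SE 0.24) and miR-450b-3p at 0.76 (SE 0.58), and miR-652-3p was at 0.38 (SE 0.22) without female replicate 3. miR-450b-3p was at 1.94 (SE 0.59) without male replicate 3. In the imprinted Dlk1-Dio3 cluster on chromosome 12, 15 of 37 miRNAs had the higher mean (median -0.05, camera adjusted p = 0.886), with miR-382-5p at 0.45 (SE 0.20). The other 3 scalings turned its sign together with a shift of all miRNAs, and relative to the median of all miRNAs the list lay between -0.04 and 0.01 under all 4.

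Among miRNA families and clusters, the median log2 fold change was 0.03 for 6 members of the miR-29 family and 0.01 for 11 of the miR-30 family, each with a camera adjusted p of 0.886. It was -0.20 for 6 members of the miR-15/16 family, where miR-15b-5p had -0.81 (SE 0.32), or -0.45 (SE 0.30) without male replicate 2, and miR-195a-5p -0.57 (SE 0.23), or -0.37 (SE 0.24) with library size alone. It was -0.14 for 14 of the miR-17 to miR-92 clusters. It was -0.20 for 4 of the miR-34 family, -0.23 for 5 estradiol-responsive miRNAs, -0.12 for 10 of the miR-23/27/24 clusters and -0.03 for 13 miRNAs of muscle growth and remodelling. The camera adjusted p of these 6 lists ran from 0.371 to 0.886. With library size alone the sign of the median turned in these lists except the miR-34 family, and that of muscle growth and remodelling turned under RLE and upper quartile factors too. Relative to the median of all miRNAs the muscle growth list lay at 0.02 and the other 5 below 0 under all 4 scalings.

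**Figure D3:**
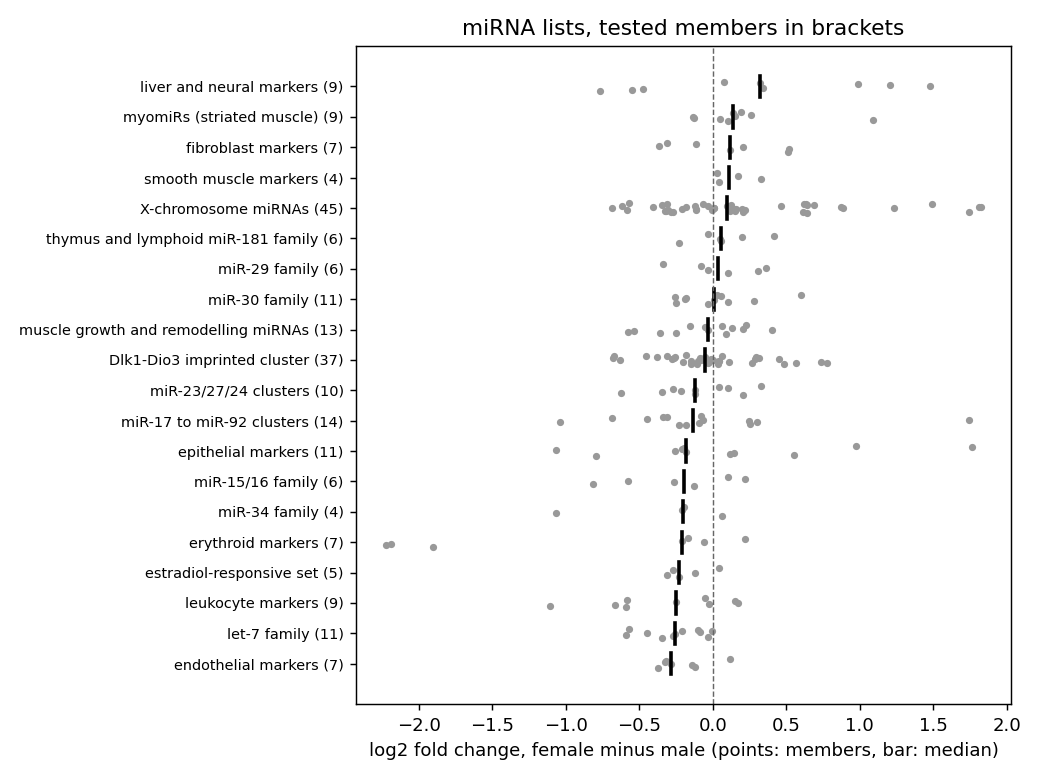
Log2 fold change, female minus male (x axis), of the tested members of each of the 20 lists (points) and the list's median (bar). All let-7 points lie below 0 under TMM scaling, 3 erythroid points lie near -2, and no list passed the camera test.

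The ratio of 5' to 3' arm counts asked whether arm use differed by sex independently of depth. Of 111 hairpins, 0 passed an adjusted p of 0.05 (limma), and 4 had an unadjusted p under 0.05. let-7d had the smallest p, with a log2 ratio of 3.92 ± 0.336 in female and 5.16 ± 0.209 in male hearts (SD, n = 4), a difference of -1.23 (SE 0.24, limma adjusted p = 0.0967). The difference was -0.75 (SE 0.23) for miR-425 and -0.77 (SE 0.31) for miR-223. mir-1306, which is outside the naming rule and was chosen after its values were seen, had a difference of 4.92 (SE 1.31) and passed only without male replicate 2. Its log2 ratio was -0.68 ± 0.534 in female and -5.60 ± 2.97 in male hearts (SD, n = 4). Few or 0 counts on an arm, where the pseudocount weighs most, were not examined as the source of that spread.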

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

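All explanations weighed in this part, and their tests, were chosen after the result was seen, and the one on miR-144-3p was written with its value already known. Of 218 groups of 4 hearts (the named miRNAs and the 3 measures of makeup in each sex), 17 held a heart far from the other 3 by Dixon's criterion. Chance sets apart 1 in 20 groups, or 10.9 of these.

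Male replicate 2 stood apart in the red cell miRNAs, with 182 CPM of miR-144-3p against 10.4 to 20.1 in the other male hearts and 104 CPM of miR-144-5p against 8.53 to 18.1. Among female hearts, replicate 2 had 17.1 CPM of miR-144-5p against 3.96 to 5.99. A candidate explanation for lower miR-451a and miR-144 in female hearts is a different amount of red blood cells left in each heart. Over the 8 hearts, deviations from the sex mean of miR-451a-5p and of the mean of both miR-144 arms went together (Pearson r = 0.891, exact permutation p = 0.00310, adjusted 0.00620, Spearman rho = 0.905, p = 0.00456, adjusted 0.00913, 4 relations tested). At p under 0.05 the relation rests on male replicate 2 and female replicate 2. Without them r was lower but still positive at 0.515 (exact permutation p = 0.286), which 6 hearts do not tell from no relation. A shared cluster would make these miRNAs vary together with any cause. Male replicate 2 alone would be enough for miR-144-3p, at 0.13 (SE 0.74) without it, while for miR-451a-5p the value without it, -1.27 (SE 0.45), leaves this open. A difference between the sexes stays open and was not tested apart from blood content.

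In male replicate 4, miR-182-5p was 2.30 CPM against 4.97 to 5.32 in the other male hearts. For the higher miR-182-5p and miR-708 in female hearts, scaling and epithelial tissue were weighed. The log2 fold change of miR-182-5p was 1.88 (SE 0.32) with library size alone, which argues against the scaling factors as the cause. The median log2 fold change of the 11 tested epithelial miRNAs was -0.18, below the level taken to speak for left epithelial tissue. Its bootstrap interval of -0.26 to 0.55 came from resampling these miRNAs and does not measure the spread between hearts. Of the 11, 5 were higher and 6 lower in female hearts. miR-429-3p was at 0.97 (SE 0.40), miR-375-3p at 1.76 (SE 1.18) and miR-34b-3p at -1.07 (SE 0.53). With members going both ways, the median does not decide on epithelial tissue. Neither miR-182-5p nor an arm of miR-708 passed the adjusted threshold in the main test. Chance and epithelial tissue therefore stay open beside a difference between the sexes.

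Further hearts apart from the other 3 of their sex were these. In male replicate 4, miR-126a-3p was 123846 CPM against 72451 to 76785, miR-208b-3p 12.3 against 8.11 to 8.69, miR-486a-5p 3799 against 4471 to 4608, and miR-221-3p 297 against 243 to 252. In male replicate 3, let-7b-3p was 5.59 CPM against 3.08 to 3.32, miR-143-3p 46206 against 58628 to 59137, and miR-222-3p 102 against 84.1 to 86.4. In male replicate 1, miR-214-3p was 83.6 CPM against 31.4 to 36.5, and in male replicate 2 miR-20b-5p was 0.324 CPM where the other 3 were at 0. That miR-20b-5p value is at about the smallest count the deposited data hold, where a 0 sets no upper limit. In female replicate 2, miR-199a-3p was 3659 CPM against 1916 to 1966 and miR-199b-3p 1826 against 956 to 981. In female replicate 3, miR-29a-5p was 19.3 CPM against 4.46 to 6.13 and miR-30c-5p 8399 against 14602 to 15816.

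Reads on hairpins outside both mature arms, not used in the comparisons, made up 2.06% of counts in male replicate 4 (Wilson 95% interval 2.05402 to 2.06356) and up to 3.08% in female replicate 4 (3.07685 to 3.08814). These intervals cover counting error only.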

How the results depend on the processing

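Mouse entries alone, the muscle share without both miR-1 entries, arm ratios from exact matches and the block with an estimated correlation were chosen after seeing the data. No miRNA was called in either direction with RLE, upper quartile or library size scaling, limma-voom, the unsummed rows (703 tested), the 10 most abundant left out, or 7 of the 8 fits with a heart left out. The number higher in female hearts was 1 with no filter, 1 with at least 10 CPM in 4 libraries, 1 with exact-match counts and 1 with mouse entries alone (miR-182-5p each time), and 3 with DESeq2. It ran from 0 to 2 with a heart left out, the 2 being miR-182-5p and miR-708-3p without female replicate 3. Fewer or more miRNAs tested change the adjustment, and otherwise the cause was not tested. Library size alone moved the median log2 fold change of all miRNAs by 0.18 and upper quartile factors by 0.10, and among miRNAs at an unadjusted p under 0.05 the split was 26 higher and 4 lower in female hearts with library size alone, 27 and 7 with upper quartile factors and 19 and 9 with RLE, against 16 and 12.

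Lists past the threshold numbered 2 with no filter (let-7 and erythroid) and 0 to 1 with a heart left out. The share of the 10 most abundant differed by -2.26 to 0.748 points with a heart left out, and the muscle share by -0.828 to 2.40, neither past the test. Arm ratios past the threshold numbered 0 to 1 with a heart left out, and the let-7d difference was -1.35 (SE 0.28) with exact matches, which argues against sequence variants as its cause. That test was made after the let-7d result was seen. Of 2065 alternative values of the 106 miRNAs under the naming rule, 72 had the other sign. A value was counted as reversed only where an unadjusted p was under 0.05, which left 0. Exact-match counts moved the log2 fold changes of miR-142a-5p to -0.38, miR-15b-5p to -0.45, miR-195a-5p to -0.36, miR-98-5p to -0.33, miR-199a-3p and miR-199b-3p to 0.98, miR-450b-3p to 1.90 and miR-652-3p to 1.05, with no sign turned. The detected number kept its sign in all alternatives run, with differences from 8.42 (without female replicate 2) to 20.4 (without female replicate 4), of 9.08 without female replicate 3 and of 8.75 at 1 CPM or more, against 14.3.

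The labels number the hearts 1 to 4 in both sexes without saying that a number pairs them. Deviations of same-numbered hearts correlated across miRNAs with r of 0.33, 0.27, 0.20 and -0.0045, and 6 of 8 hearts correlated best with their own number, with pair 4 as the exception, which is a hint from the data that some numbers pair hearts. Not all 4 pairs deviated together and the labels state no pairing, so the hearts were not treated as pairs, and a pairing was not excluded. With the replicate block, 1 miRNA was higher in male hearts (miR-144-5p, adjusted p = 0.0209), 0 were higher in female hearts and 2 lists passed (erythroid with adjusted p = 8.01e-05 and let-7 with 0.0411), and 0 lists passed when the correlation was estimated as well.

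Each of the 35 splits of the 8 hearts into 4 and 4 gave at least the real 0 miRNAs past the threshold (highest other 0), at least the real 0 lists (highest other 3) and at least the real 0 arm ratios (highest other 0). That holds for any count of 0 and says nothing about chance. At an unadjusted p, 10 of 35 splits gave at least the real 28 (median of the others 17.5, highest other 73), so chance cannot be excluded. The other splits at 28 or more all put female and male replicate 1 together. This may point to a structure other than sex, seen afterwards and not tested. Splits that part same-numbered pairs follow below.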

Other observations

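All relations in this part were chosen after results were seen. That with the leukocyte miRNAs was first computed with 4 of them and then with the whole tested list, which is the one given. In a principal component analysis of log2 CPM, the first component (25.5% of variance) did not separate the sexes (two-sided exact permutation p = 0.514). The second (19.8%) put all 4 female hearts below all 4 male hearts (exact permutation p = 0.0286, the smallest the 70 arrangements give, adjusted over 2 components 0.0571). Female replicate 1 and male replicate 1 lay lowest on the first component, at -10.8 and -14.0, against -3.90 to 12.3 for the other 6 hearts. Some splits of the hearts into 4 and 4 put the hearts of every same-numbered pair on opposite sides. Among these, the split by sex had the most miRNAs at an unadjusted p under 0.05, with 28 against 8 to 19. This subset was chosen after the counts were seen and holds too few splits to exclude chance.

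The red cell miRNA miR-451a-5p also went with the leukocyte miRNAs. Deviations from the sex mean of miR-451a-5p and of the mean of the 9 tested leukocyte miRNAs had r = 0.760 (exact permutation p = 0.0297, adjusted 0.0396, Spearman rho = 0.762, p = 0.0368, adjusted 0.0490). Without male replicate 2 and female replicate 2 r was lower but still positive at 0.562 (exact permutation p = 0.242), so its p rests on those hearts, and 6 hearts do not tell such an r from no relation. With the summed 5' arms of miR-486a and miR-486b, r was -0.293 (exact permutation p = 0.489, adjusted 0.489, rho = -0.310, p = 0.462, adjusted 0.462), and -0.0764 without the same 2 hearts.

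A rat entry, miR-3557-5p, was among the 10 most abundant with a mean of 35069 CPM. It may hold reads of the miR-378 family, which is abundant in heart and whose 14 entries summed to 20394 CPM. Over the 8 hearts the log2 CPM of both went together with Pearson r = 0.941 (exact permutation p = 2.48e-04, adjusted 9.92e-04) and Spearman rho = 0.952 (p = 0.00114, adjusted 0.00456), and r was 0.850 (exact permutation p = 0.0306) without male replicate 1 and female replicate 3. Of 57 other miRNAs with at least 1000 CPM, 0 had an r as high, the next being miR-151-3p, chosen after its values were seen, at 0.875. Sequences were not compared, so 2 abundant miRNAs that vary together would give the same r.

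Several other hairpin pairs on opposite strands held counts that cannot be assigned. The 5' arm entries of mir-3074-1 and mir-3074-2, opposite mir-24-1 and mir-24-2, held 756987 and 756962 counts over the 8 libraries with 51 and 53 exact matches, while the mir-24 3' entries held 225387 and 225396 with 0 exact matches. A rat mir-133c 5' entry held 7088 ± 1609 CPM in female and 5596 ± 608 CPM in male hearts (SD, n = 4), against 286 ± 85.5 and 266 ± 25.9 CPM for the 5' arm of miR-133a. The mir-3074 and mir-133c entries were chosen after their values were seen.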
